A study of Mus musculus with 3 samples.

How the data were processed

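Single-cell RNA libraries of regulatory T cells (Tregs) from mouse epidermis, dermis and lymph node were analysed, with 1 library per tissue. Per the labels, the mice were adults of the Foxp3-EGFP strain C.Cg-Foxp3tm2Tch/J. Per the labels' protocols, thermolysin separated the skin layers, dermis was also digested with collagenase, lymph node was mashed, and GFP+ CD4+ CD3+ CD45+ cells were sorted. Per the labels' protocols, epidermal and dermal cells were run with the 10x Genomics 3′ v3 kit and lymph node cells with the v2 kit. Mapping was to mm10 with Cell Ranger, per the submitters' processing notes. The version was 4.0.0 for both skin libraries, per the file headers, and is not given in the sources used here for lymph node. The number, age in weeks and sex of the animals behind each library are not given in the sources used here.

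The deposited values were counts, that is, raw UMI counts per gene and cell barcode with no normalization. Whole numbers and unequal totals between barcodes were checked in all 3 matrices. Each matrix held barcodes already called as cells: 360 for epidermis, 1077 for dermis and 9419 for lymph node. All 3 libraries shared a table of 27998 genes, in which 13 genes of the lists used here were missing, among them the constant genes of the T cell receptor. Mapping, barcode calling and the raw reads were not analysed here.

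A barcode was kept with at least 500 UMIs, at least 300 genes, at most 10% mitochondrial UMIs, at least 2 UMIs of T cell genes and at most 3% of UMIs on marker genes of other cell types. Of the 7 T cell genes chosen, 4 were in the gene table (Cd3d, Cd3e, Cd3g and Cd4). The mitochondrial limit removed 63 epidermal, 202 dermal and 19 lymph node barcodes, and 24, 37 and 100 further barcodes passed the quality filter but lay outside the gate. The gate left 271 epidermal cells with 2188897 UMIs, 838 dermal cells with 4532978 UMIs and 9300 lymph node cells with 32676431 UMIs. Median genes per cell were 2145, 1699.5 and 1158. Doublets were scored with Scrublet in scanpy and left in the main values; it marked 14, 10 and 5 cells, and 0.0538% of lymph node cells is too few for the method to have worked there.

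UMIs of each gene were summed over the gated cells of a library and given as CPM, the count scaled to a common library total. The ratio of 2 libraries had an exact 95% interval from the binomial split of both counts, which covers counting error only. With 1 library per tissue, cells are not replicates and no test between tissues was run. A gene was counted as higher or lower when the ratio reached 2-fold and the higher library had at least 50 CPM. A ratio against 0 UMIs was computed against a floor of 3 counts and is a lower bound. Shares of cells with a UMI were computed after thinning each cell to 1500 UMIs, with exact Clopper-Pearson intervals.

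A set of 20 functional gene lists was fixed before the data were examined, as were 10 marker lists of other cell types and 3 of other T or innate lymphoid cells. For each functional list the median log2 ratio was taken over members with at least 10 CPM in 1 of the libraries compared. Counts of higher and lower members kept the limit of 50 CPM, so a member not counted could still differ by 2-fold or more. Its percentile came from 10000 random lists of the same size, matched on expression in 10 bins. A list was called apart at a percentile of at most 2.5 or at least 97.5. The range beside a list's median reflects counting error of its members.

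The named genes followed a rule fixed before the data were examined. It took 12 genes in every comparison (Foxp3, Il2ra, Ctla4, Gata3, Areg, Il1rl1, Ccr8, Itgae, Itgb8, Cd69, Ccr7 and 1 that is not reported here). It added the 10 highest and 10 lowest ratios, leaving out mitochondrial, ribosomal protein, predicted, immune receptor segment, sex-linked, haemoglobin and keratin genes and other-type markers. It also added up to 4 members per functional list with the largest ratios at 50 CPM or more. Symbols, gene identifiers and positions were those of the matrices and of the GENCODE vM21 annotation of mm10.

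Clusters were made within each library from 1500 variable genes, 20 principal components, 15 neighbours and Leiden resolution 1. A cluster could take the name of a type when at least 5 markers of that type were at least 1.5-fold above the rest at 20 CPM or more. Of such types it took the one with the most markers among the cluster's 10 leading genes, with at least 1 required and ties going to the type with more raised markers. This naming rule was chosen after the clusters were seen, while the marker lists were fixed before. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.

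Alternatives fixed beforehand were other cell filters, cells with a Foxp3 UMI, removal of doublets, the mean of each cell's CPM, thinned cells, median-of-ratios and TMM scaling, totals without mitochondrial and ribosomal protein genes, limits of 20 and 100 CPM, intervals beyond 2-fold, lymph node cells of effector Treg-like clusters only, and other thinning depths. Alternatives chosen after seeing the data were cells with Xist and no Y-linked UMI, leaving out the resting Treg-like clusters, a mitochondrial limit of 20%, leaving out cells above the 95th UMI percentile, leaving out immediate early-high clusters, and leaving out cycling clusters. The Xist setting was first run on every comparison and the immediate early setting on gene counts as well; both were narrowed, after those values were seen, to the skin comparison and to the lists. The lists were also computed between the skin layers in cells with Y-linked and no Xist UMI, chosen after the data were seen.

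The steps were tested on simulated data, with 200 genes changed by known folds. At 3-fold, 100% of changed genes were called in each of the 3 comparisons. At 5-fold, 95.2% were called between epidermis and dermis (2847 genes run), and 100% between epidermis and lymph node (2380 genes) and between dermis and lymph node (2372 genes). At 1.5-fold 0% were called, and 0 unchanged genes were called in any comparison. The simulation drew counts of whole libraries and held counting error only. That error hardly reaches 2-fold at these depths, so the absence of calls among unchanged genes was nearly fixed in advance. It gives no rate of false calls from a few cells, animals or preparations. Of 100 unchanged lists, 3, 2 and 3 were called apart in the same order of comparisons.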

Results

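Tregs are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. Single-cell RNA counts were collected from Tregs of mouse back epidermis, dermis and lymph node, sorted by the green fluorescence of a Foxp3 reporter strain. The design sets the Tregs of the skin layers beside each other and beside lymph node Tregs. The epidermal library held 271 gated cells, the dermal library 838 and the lymph node library 9300, with median depths of 7052, 4813 and 3033.5 UMIs (unique molecular identifiers) per cell. Each tissue had 1 library, so no test between tissues was possible. The lymph node library was made with the v2 kit and both skin libraries with v3, so each difference from lymph node was also a difference of kit.

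After gating, transcripts of other cell types were low in all 3 libraries. Keratinocyte markers summed to 75.4 CPM in epidermis, 102 in dermis and 33.6 in lymph node. Dendritic and Langerhans cell markers summed to 413, 409 and 192 CPM, of which Cd74 made up 367, 364 and 166 CPM. Markers of fibroblasts, endothelial and mural cells, macrophages, mast cells, neutrophils, B cells, melanocytes and erythroid cells had their highest sum at 85.0 CPM, for endothelial and mural markers in lymph node. Pecam1 alone made up 84.7 CPM of that sum. CD8 T and NK cell markers summed to 47.5, 20.3 and 21.5 CPM. The innate lymphoid list reached 889, 1664 and 237 CPM, led by Il7r in epidermis and lymph node and by Rora in dermis, which T cells also express. The gamma-delta T cell list had 2 of 8 genes in the gene table, with no UMI in any library. The libraries differed in transcripts that mark sex: Y-linked UMIs were found in 37.3% of epidermal cells, 8.35% of dermal cells and 0 of 9300 lymph node cells (upper 95% limit 0.0397%). Xist UMIs were found in 40.6%, 85.8% and 75.5% of cells.

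Areg encodes the growth factor amphiregulin (chromosome 5, 91139599 to 91148432, mm10). It stood at 529 CPM (95% interval 499 to 560) in epidermis, 762 CPM (737 to 788) in dermis and 4.35 CPM (3.66 to 5.12) in lymph node. Ctla4, an inhibitory receptor through which Tregs act (chromosome 1, 60887000 to 60915832), stood at 1127, 2262 and 166 CPM. Foxp3 (chromosome X, 7573644 to 7595245) stood at 91.8 CPM (79.6 to 105), 147 CPM (136 to 159) and 21.8 CPM (20.2 to 23.5). Itgae encodes the CD103 integrin chain that binds E-cadherin on epithelial cells (chromosome 11, 73090583 to 73147446), and stood at 471, 426 and 56.9 CPM. The interleukin 2 receptor gene Il2ra differed less, at 386, 315 and 214 CPM, and the homing receptor gene Ccr7 was highest in lymph node, at 142, 73.0 and 224 CPM.

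**Figure D1:**
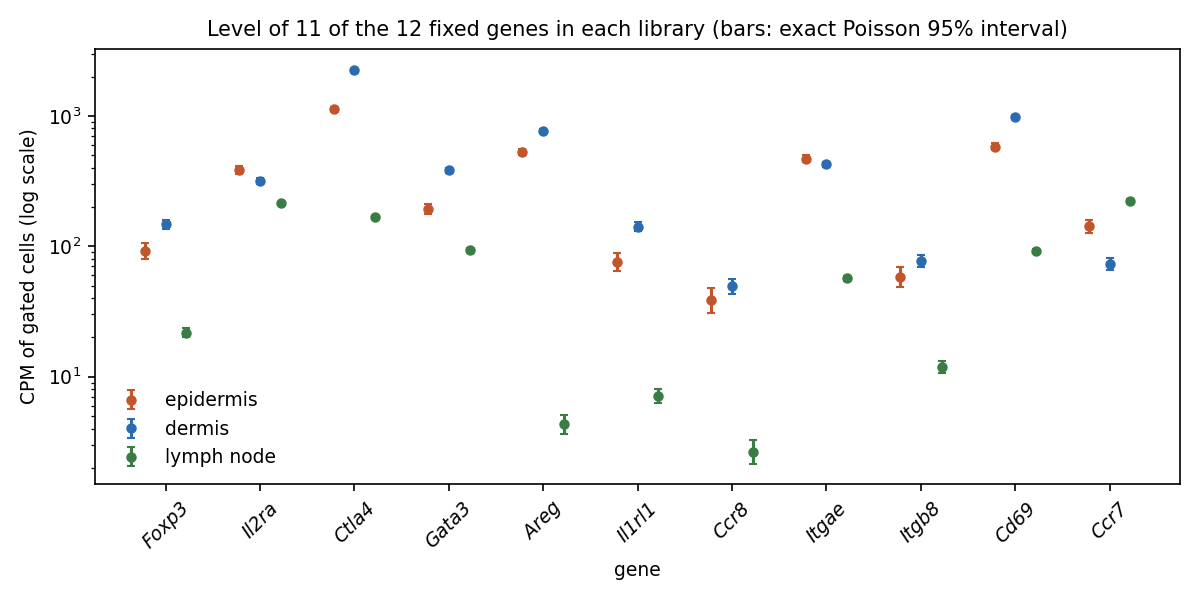
CPM of 11 of the 12 genes fixed before the data were examined (log axis) in the epidermal, dermal and lymph node libraries, 1 library each, with exact Poisson 95% intervals. Areg stood at 529, 762 and 4.35 CPM and Itgae at 471, 426 and 56.9 CPM in that order.

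Foxp3 transcripts were seen in a larger share of skin than of lymph node cells. At 1500 UMIs per cell, 16.8% of 262 epidermal cells (exact 95% interval 12.5 to 21.9), 20.1% of 815 dermal cells (17.4 to 23.0) and 3.45% of 9211 lymph node cells (3.09 to 3.85) had a Foxp3 UMI. Without thinning, the shares were 43.2%, 48.6% and 7.18%. Among sorted cells outside the gate, 4.17% of 24 epidermal, 10.8% of 37 dermal and 6% of 100 lymph node cells had a Foxp3 UMI, at median depths of 575.5, 1282 and 2157.5 UMIs. The lymph node share thus lay within the interval of the cells outside its gate (2.23 to 12.6). Of those 100 cells, 95 were left out for having under 2 T cell UMIs and 38 had an Il2ra UMI, so they were not shown to be another cell type and give no background level.

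Compared with dermis, the epidermal library carried more transcripts of resting T cells, of the interferon response and of proliferation. It carried fewer transcripts of the immediate early and dissociation group and of the effector Treg programme. The lymphoid homing and resting group had a median ratio of 2.5 (log2 1.32). Of its 19 measured members, 8 were counted as at least 2-fold higher in epidermis, none as lower, and 11 were not counted. Here and below, counted list members also had at least 50 CPM in the higher library. Members not counted include scarcer ones that differed by 2-fold or more, so these counts can understate a list. The survival gene Bcl2 was 14.1-fold higher (9.85 to 20.7, at 109 against 7.72 CPM), the actin regulator Evl 10.3-fold and the chromatin organiser Satb1 8.56-fold. Their calls held in 14, 13 and 13 of 15 alternative settings, and the lowest log2 ratio of Bcl2 among these was 0.50. Interferon response genes had a median log2 ratio of 0.84, with 5 of 22 at least 2-fold higher and none lower. Among these, the GTPase gene Iigp1 was 4.32-fold higher, Ifi47 2.74-fold and Gbp2 2.49-fold. In total, 82 of 3061 genes with at least 50 CPM were at least 2-fold higher in epidermis and 140 were at least 2-fold lower, as a difference between these libraries with no replicate check.

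Proliferation genes had a median log2 ratio of 1.56 between epidermis and dermis. Of 20, 7 were counted as at least 2-fold higher at 50 CPM or more and none as lower. The median lies above 2-fold, so further, scarcer members were also at least 2-fold higher. Rrm2, a subunit of ribonucleotide reductase, was 7.06-fold higher, the mitotic gene Birc5 6.82-fold, Stmn1 5.22-fold and Mki67 3.81-fold. A cluster of 8 epidermal cycling-like cells, with a median of 20241 UMIs, held 47.8% of the epidermal UMIs of this group and 8.32% of all epidermal UMIs. Without the cycling clusters of all libraries, the log2 median was 0.90, Rrm2 stood at 1.27, Birc5 at 2.11, Mki67 at 0.27 and Stmn1 at 2.02. That Birc5 value rested on 2 epidermal UMIs against 1 dermal UMI and shows no difference outside the cycling cells. Without cells above the 95th UMI percentile, Rrm2 stood at -0.12. The call of Rrm2 held in 11 of 15 alternative settings and that of Birc5 in 6. The histone genes Hist1h2ap (8.45-fold higher) and Hist1h2ae (6.68-fold) share sequence with other histone genes and are uncertain; without those clusters their log2 ratios were 0.94 and -0.05. The chemokine gene Ccl4 was 13.1-fold higher, with all of its UMIs in 14 epidermal and 5 dermal cells.

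Of the Treg core genes, 3 of 17 were counted as at least 2-fold higher in epidermis than in dermis and 1 as lower. The other 13 were not counted, and the median log2 ratio was 0.29. Izumo1r, which encodes a folate receptor of Tregs, was 8.15-fold higher, Nt5e (the ectoenzyme CD73) 3.54-fold and Ikzf4 2.18-fold. Ctla4 was 2.01-fold lower (1.92 to 2.10) and met the 2-fold limit in 6 of 15 alternative settings. Foxp3 was 1.6-fold lower (1.36 to 1.88). Restricted to cells with a Foxp3 UMI, the median of the group was -0.02. Oxidative phosphorylation genes had a median of 0.28, with none of 20 counted at 2-fold. Ndufa4 was 1.43-fold higher and Atp5g1 1.42-fold.

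Immediate early and dissociation genes had a median log2 ratio of -0.91, with 10 of 23 at least 2-fold lower in epidermis than in dermis and none higher. The inducible heat shock genes Hspa1b and Hspa1a were 10.5-fold and 9.46-fold lower; they are near-identical paralogs that share reads, so their separate values are uncertain, and 5 of 838 dermal cells held 46.0% and 44.2% of their dermal UMIs. The transcription factors Atf3 and Fosb were 4.27-fold and 4.23-fold lower. The chemokine gene Cxcl2 was 11.1-fold lower, Klf4 5.81-fold and the nuclear lamin gene Lmna 4.27-fold. In the T cell receptor activation group (median -0.41), 3 of 19 genes were lower, Tnfaip3 by 2.40-fold, Nr4a1 by 2.18-fold and Nr4a3 by 2.02-fold, the last of which met the 2-fold limit in 5 of 15 alternative settings. Irf8 was 3.72-fold higher.

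Effector and tissue Treg genes had a median log2 ratio of -0.53. Of 23, 2 were counted as at least 2-fold lower in epidermis, none as higher, and 21 were not counted. Rora was 2.48-fold lower and Klrg1 2.11-fold, calls held in 12 and 10 of 15 alternative settings. In the type 2 group (median -0.65) none of 7 genes was counted at 2-fold: Gata3 was 1.98-fold lower and Il1rl1, the receptor for interleukin 33, 1.86-fold. In the residency group (median -0.32), 4 of 16 genes were lower, and Cxcr6 was 2.35-fold higher. The lower genes were led by the heat shock gene Hspa1a, which is also in the immediate early group and whose separate value is uncertain. The others were Rgs2 (2.54-fold), Crem (2.51-fold) and Vps37b. In the chemokine receptor group (median -0.23), Ccr10 was 4.10-fold lower and Gpr55 2.22-fold, while Cxcr6 and Cxcr3 (2.09-fold, a call held in 7 of 15 alternative settings) were higher. Cytokine genes had a median of -0.43 and a mean of 0.14, with none of 11 counted at 2-fold. Il10 was 1.71-fold lower and Areg 1.44-fold lower. The TGF-beta group had a median of -0.25 and a mean of 0.05, with Pmepa1 3.81-fold higher and Tgif1 2.09-fold lower, the latter a call held in 8 of 15 alternative settings. The call of the list was kept in 4 of 17 alternative settings and lost in the others, and its median was positive in 4. List calls were kept in 11 of 17 for chemokine receptors, 12 for the Treg core and for cytokines, 13 for oxidative phosphorylation and 14 for residency.

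Median log2 ratios between epidermis and dermis were not apart from random lists in the other 7 functional groups. They were -0.10 for integrins and adhesion, 0.0035 for co-inhibitory receptors, 0.20 for glycolysis and hypoxia, -0.19 for the type 17 group and 0.02 for the type 1 group. Lipid genes had a median of -0.0027 and a mean of 0.07, with Dgat1 3.50-fold lower and Fdps 2.11-fold higher, the latter held in 6 of 15 alternative settings. Cytotoxic genes had a median of -0.06 and a mean of 0.12, with the protease gene Ctsw 5.18-fold higher. Pgk1 was 2.72-fold higher, and Itgae (1.10-fold higher), Itgb8 (1.33-fold lower) and Cd69 (1.70-fold lower) did not reach 2-fold.

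The balance of higher and lower genes between the skin layers moved with the scaling. The median gene stood at log2 0.01 by CPM, -0.12 by TMM and 0.14 on totals without mitochondrial and ribosomal protein genes, with 36.9%, 24.2% and 57.0% of called genes higher in epidermis; with median-of-ratios scaling the share was 25%. Without the resting Treg-like clusters of both libraries, the resting group stood at 0.16 and was not apart. In cells with Xist and no Y-linked UMI (107 epidermal and 703 dermal), the resting group stood at 0.92 and the immediate early group at -0.58, with residency at 0.04, T cell receptor activation at 0.16 and cytokines at 0.07. In cells with Y-linked and no Xist UMI (98 and 54), the resting group stood at 0.97, the immediate early group at -1.37, residency at -0.66, T cell receptor activation at -0.59 and cytokines at -0.080.

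**Figure D2:**
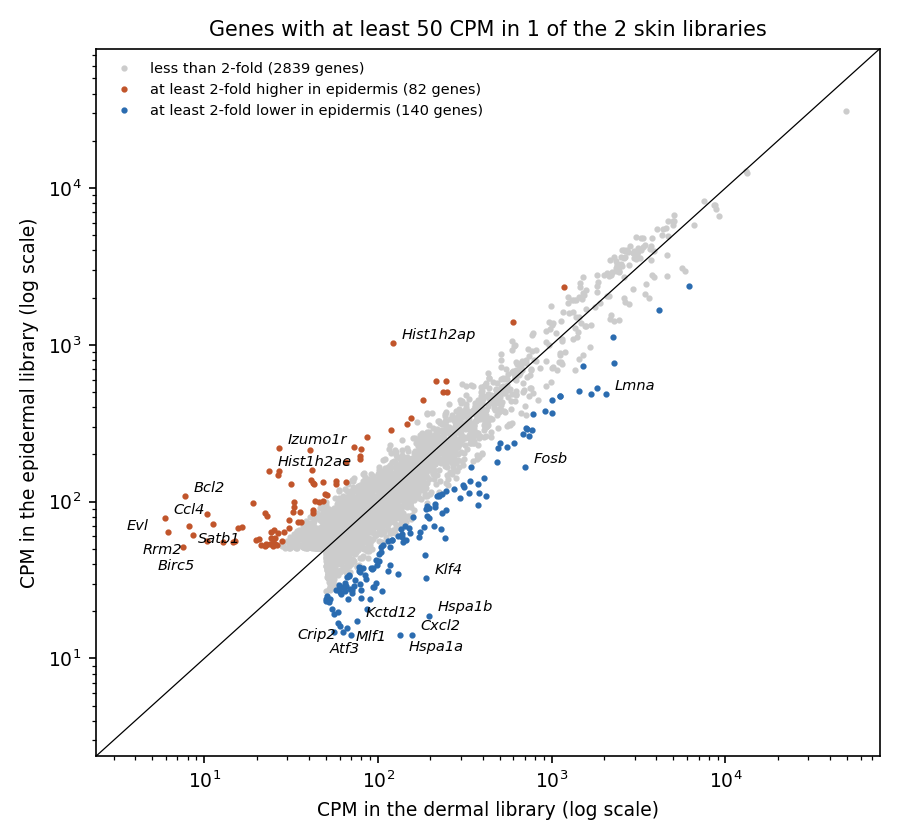
Epidermal against dermal CPM (log axes) of the 3061 genes with at least 50 CPM in either library, 1 point per gene and 1 library per tissue; the line marks equal CPM. Genes at least 2-fold higher in epidermis (82) include Bcl2 and Evl, and those lower (140) include Cxcl2, Hspa1b and Lmna.

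Compared with lymph node, the epidermal library carried more transcripts of the effector, residency, TGF-beta and activation programmes and fewer of lymphoid homing. Of 23 effector and tissue Treg genes, 17 were counted as at least 2-fold higher in epidermis, none as lower, and 6 were not counted. The median ratio was 5.84 (log2 2.55). Ccr8, at 38.8 CPM in epidermis and 2.66 in lymph node, is a gene that the limit of 50 CPM kept from being counted. Areg was 122-fold higher (102 to 146), the suppressive cytokine gene Il10 23.3-fold, S100a4 13.0-fold and Il1rl1 10.6-fold. Of the lymphoid homing and resting genes (median log2 -0.66), 7 of 20 were lower and Il7r was higher. Among them Bcl2 was 4.32-fold lower and Evl 4.27-fold, while Ccr7 was 1.58-fold lower. In total, 569 of 3066 genes were at least 2-fold higher in epidermis and 106 were lower, with no replicate check.

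Genes of tissue residence and migration stood higher in epidermis than in lymph node. In the residency group, 11 of 17 were higher and none lower (median log2 2.66), including Cxcr6 (14.6-fold), Rgs2 (9.80-fold), Itgae (8.28-fold) and Cd69 (6.32-fold). In the chemokine receptor group, 8 of 20 were counted as higher (median 1.66), led by Cxcr4 (28.9-fold), with Gpr55 at 8.62-fold and Ccr2 at 6.50-fold. In the TGF-beta group, 9 of 16 were higher (median 1.17). These included the protease gene Furin (11.5-fold), the induced inhibitor Pmepa1 (10.9-fold) and both chains of the TGF-beta activating integrin, Itgav (9.81-fold) and Itgb8 (4.89-fold). In the integrin and adhesion group 7 of 18 were higher and 1 was lower (median 0.61).

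In the immediate early and dissociation group, 11 of 22 were higher in epidermis than in lymph node and none lower (median log2 2.21), with Fosb at 247-fold (161 to 399), Fos at 83.6-fold and Dusp1 at 19.9-fold. Skin was enzyme-treated and lymph node mashed, and 17.5% of epidermal and 18.8% of dermal barcodes lay over the mitochondrial limit against 0.202% in lymph node, so a difference of handling cannot be separated from the tissue here. In the T cell receptor activation group 11 of 20 were higher (median 1.38), including Tnfaip3 (15.3-fold), Nr4a3 (12.9-fold) and Nr4a1 (9.76-fold). In the co-inhibitory group (median 0.92), Ctla4 was 6.78-fold higher and Klrg1 5.38-fold, with 5 of 14 higher and 2 lower. In the Treg core (median 0.79), Foxp3 was 4.21-fold higher (3.59 to 4.94), while Gpr83 was 5.55-fold lower and Izumo1r 4.01-fold lower. In cells chosen for having a Foxp3 UMI, Foxp3 itself stood at log2 -0.33. Medians were 1.87 for cytokines, 1.06 for the cytotoxic group with Gzmb 7.53-fold higher, 1.58 for type 1, 1.54 for type 17 and 1.3 for type 2.

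In glycolysis and hypoxia, 7 of 19 genes were counted as higher in epidermis than in lymph node and 1 as lower (median log2 1.10). The higher genes included the oxygen-sensing factor Hif1a at 3.51-fold. Pgk1 (10.8-fold) and Tpi1 (4.46-fold) have pseudogenes that can take or lend reads and are uncertain. Not apart from random lists were oxidative phosphorylation (-0.13), lipid genes (0.78) and the interferon response (-0.08), within which 1 of 22 was higher (Ly6a, 2.31-fold) and 3 were lower, with Usp18 at 3.91-fold and Ifit1 at 3.69-fold. Proliferation genes had a median of 1.20, and of 0.84 without the cycling clusters. Birc5 then stood at -0.97, on 2 epidermal UMIs against 62 in lymph node, and its call held in 6 of 14 alternative settings. The trefoil peptide gene Tff1 was 54.3-fold higher, with log2 ratios from 3.297 to 6.085 over 14 alternative settings. Lars2 (66.1-fold higher) and Wdr89 (27.8-fold lower) are uncertain, since related sequences can share their reads. Id3, a regulator of T cell differentiation, was 6.19-fold lower.

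The balance of this comparison depended on the scaling as well as on the kit. The median gene stood at log2 0.13 by CPM, -0.28 by median-of-ratios, -0.39 by TMM and -0.08 without mitochondrial and ribosomal protein genes, with 84.3%, 53.3%, 42.2% and 71.4% of called genes higher in epidermis, and every ratio is to be read against these medians. List calls were kept in 12 of 16 alternative settings for co-inhibitory receptors and in 13 for integrins and for proliferation.

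Compared with lymph node, the dermal library carried the effector and immediate early programmes at high levels and little of the resting programme. Of 23 effector and tissue Treg genes, 17 were counted as at least 2-fold higher in dermis, none as lower, and 6 were not counted. The median ratio was 9.40 (log2 3.23). Areg was 175-fold higher (148 to 209), Il10 39.8-fold, Rora 22.0-fold and S100a4 21.7-fold. Of the lymphoid homing and resting genes (median log2 -2.17), 11 of 20 were lower and Il7r was higher. The transcription factor gene Tcf7 was 73.8-fold lower, Bcl2 60.9-fold and Evl 43.9-fold. In total, 824 of 3199 genes were at least 2-fold higher in dermis and 307 were lower, with no replicate check.

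Immediate early genes were higher in dermis than in lymph node in 17 of 23 cases and lower in none (median log2 3.18). Fosb was 1045-fold higher (689 to 1669) and Fos 290-fold. Hspa1a (729-fold) and Hspa1b (586-fold) share reads and are uncertain as separate values. Atf3 had no UMI in lymph node and was at least 680-fold higher against a floor of 3 counts over that library. Klf4 was 440-fold and Cxcl2 394-fold higher. In the T cell receptor activation group (median 1.94), 11 of 20 were higher and 1 was lower, with Tnfaip3 at 36.8-fold and Nr4a1 at 21.3-fold. Interferon response genes went the other way (median -0.79), with 9 of 22 lower and none higher, including Usp18 (18.0-fold lower) and Ifit1 (11.2-fold lower).

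Residency genes had a median log2 ratio of 2.63 between dermis and lymph node, with 11 of 17 higher and none lower, including Rgs2 (24.9-fold), Cd69 (10.7-fold) and Itgae (7.50-fold). The largest ratio was that of the heat shock gene Hspa1a, which is also in the immediate early group. In the chemokine receptor group (median 2.07), 10 of 19 were higher and none lower. Cxcr4 was 34.0-fold higher and the skin-homing receptor Ccr10 20.7-fold. TGF-beta genes had a median of 1.02 with 7 of 17 counted as higher and 1 as lower, and Itgav (19.3-fold), Smad7 (8.39-fold) and Itgb8 (6.52-fold) were higher. In the type 2 group (median 2.04) Il1rl1 was 19.8-fold, Gata3 4.12-fold and Ccr4 3.88-fold higher. Ctla4 was 13.6-fold higher and Foxp3 6.74-fold (6.06 to 7.51), while in the same Treg core group (5 of 17 higher, 5 lower, median 0.73) Gpr83 was 37.1-fold and Izumo1r 32.7-fold lower. Among other genes, Capn3 was 90.4-fold lower (30.9 to 439) on 3 dermal UMIs, Ms4a4c 69.5-fold and Tbc1d4 40.8-fold.

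Median log2 ratios of the remaining groups between dermis and lymph node were 1.07 for co-inhibitory receptors, 0.95 for integrins, 1.05 for glycolysis and hypoxia, 0.99 for lipid genes and 2.03 for cytokines, with 1.69 for type 17 and 1.63 for type 1. Oxidative phosphorylation had a median of -0.51, with Ndufs6 2.35-fold lower as the 1 of 20 genes counted at 2-fold. Not apart were cytotoxic genes (0.76), although Gzmb was 10.5-fold higher and Ctsw 4.98-fold lower, and proliferation (-0.40). By median-of-ratios, TMM and totals without mitochondrial and ribosomal protein genes, the median gene moved from log2 0.15 to -0.17, -0.29 and -0.25, and the share of called genes higher in dermis from 72.9% to 54.2%, 45.6% and 47.9%. On the last of these scalings the co-inhibitory median was -0.20. List calls were kept in 12 of 16 alternative settings for co-inhibitory receptors and for the Treg core, and in 13 for type 1. For type 17 the call was kept in 14, and its median was -0.32 against lymph node effector Treg-like clusters only.

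**Figure D3:**
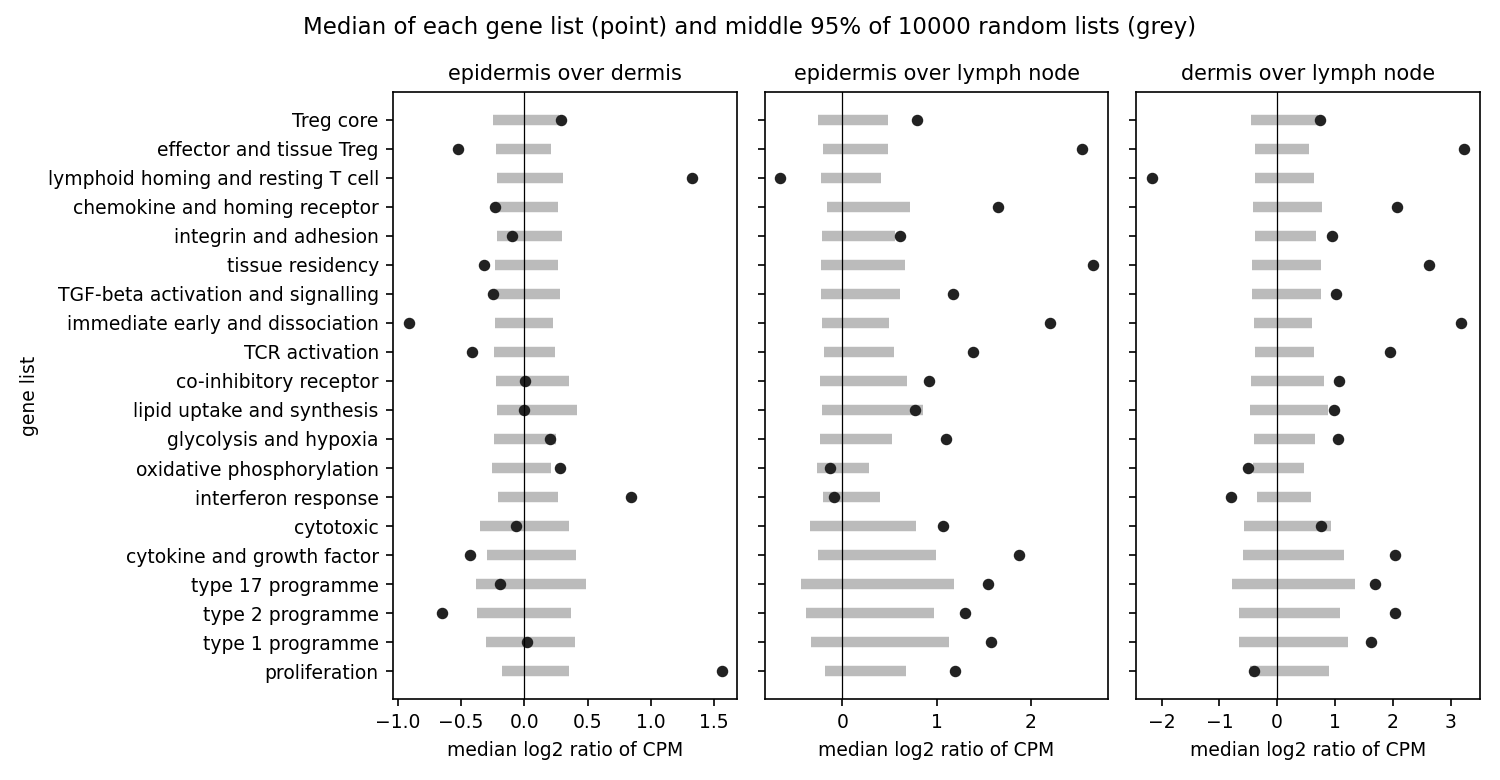
Median log2 ratio of 20 gene lists in the 3 comparisons of libraries, with the middle 95% of matched random lists as the band for each. The effector and tissue Treg list stood at -0.53 for epidermis over dermis, 2.55 for epidermis over lymph node and 3.23 for dermis over lymph node.

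Both skin layers differed from lymph node in overlapping genes. Of 2954 genes with at least 50 CPM in both comparisons, 478 were at least 2-fold higher in both skin libraries than in lymph node, among them Areg, Ctla4, Itgae and Cd69, and 101 were lower in both, among them Bcl2 and Evl. By median-of-ratios scaling these counts were 298 and 256, and by TMM 258 and 340. No gene was called in opposite directions. Among these genes, 518 were higher in epidermis and 647 in dermis, and 106 and 307 were lower. Independent lists of these sizes would share 113 and 11 genes. Unchanged libraries simulated against the same lymph node counts shared 0. That simulation held counting error only, which hardly reaches 2-fold at these depths, so its outcome was nearly fixed and does not explain the overlap. Part of the excess may come from the single lymph node library that both comparisons share. The kit and the enzyme treatment, which both skin libraries share against lymph node, may contribute too, and these parts cannot be split.

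Set against the 1096 lymph node cells of effector Treg-like clusters only, fewer genes were higher in skin. In epidermis 324 were higher, against 569 set beside all lymph node cells, in dermis 568 against 824, and in both skin layers 262 against 478. Lower genes numbered 98 against 106 in epidermis and 325 against 307 in dermis. Only 54 of those 98 and 222 of those 325 were also lower against all lymph node cells. Areg remained far above these cells, at log2 5.74 in epidermis and 6.27 in dermis, as did Fos (5.40 and 7.19) and Cxcr4 (4.55 and 4.79). Below 2-fold in epidermis were then, among others, Itgb8 (0.93), Gpr55 (0.89), Gzmb (0.45), Gata3 (0.35), Ccr2 (0.24) and Klrg1 (-0.088), and in dermis Gzmb (0.93) and Ccr4 (0.095), all called against all lymph node cells. Ctla4 stood at 1.23 and 2.23, Itgae at 1.03 and 0.88, Il1rl1 at 1.38 and 2.28, and Foxp3 at 1.89 and 2.57. The residency group stood at 1.22 and 1.38 and the TGF-beta group at 1.00 and 0.75, and both stayed apart from random lists in both skin layers. The Treg core (0.02 and 0.06) and co-inhibitory groups (-0.29 and 0.24) did not. The resting group stood at 0.11 in epidermis, no longer apart, and at -1.21 in dermis. The effector marker list that named these clusters held, among others, Klrg1, Gata3, Ccr2, Il1rl1 and Itgae. Klrg1, Gzmb and Ccr2 were also among the leading genes of the larger cluster. These genes, the effector group (0.83 and 1.34) and other groups that hold them are thus not independent of the selection. That selection can by itself lower their ratios, and the kits still differed.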

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

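Among the tests in this part, those on Foxp3 at equal depth, on Foxp3 in effector cells, on free RNA, on cells with Y-linked and no Xist UMI and on collagenase were chosen only after the result was seen, as was the setting without resting Treg-like or immediate early-high clusters and that of cells with Xist and no Y-linked UMI.

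Cells outside the gate, which no main ratio used, carried markers of other cell types. In dermis, 37 such cells held 490 UMIs of keratinocyte markers and 594 of endothelial and mural markers; the 176 Krt14 UMIs lay in 1 cell and the 254 Fabp4 UMIs in 2 cells. In lymph node, 100 such cells held 914 UMIs of dendritic and Langerhans markers, with Cd74 at 572 UMIs in 28 cells, and 146 of B and plasma cell markers, with Cd79a at 62 UMIs in 8 cells. The sort for CD3+ CD4+ cells should have removed all of these types.

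Transcripts that mark sex were left out of the ranking of named genes, though not of the gene counts. Gated cells held 253 Y-linked UMIs in epidermis and 125 in dermis, against 0 in the far larger lymph node library. Only 3 epidermal and 16 dermal cells held both Xist and Y-linked UMIs.

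The median log2 ratio of proliferation genes to lymph node had opposite signs in the skin layers, 1.2 for epidermis and -0.40 for dermis, of which the dermal one was not apart from random lists. Directly between epidermis and dermis it was 1.56 and apart. The epidermal value against lymph node rests in part on 8 cycling-like cells, without which, and without the cycling clusters of the other libraries, it was 0.84.

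Foxp3 UMIs were found in a smaller share of lymph node than of skin cells. Lower depth was argued against, since at equal UMIs per cell the dermal share was still 5.83 times the lymph node share, and so was an effector state as the whole source, since lymph node effector Treg-like cells held 0.169 (0.137 to 0.206) of the dermal Foxp3 CPM. Cells other than Tregs, which the sort for the Foxp3 reporter should have removed, were argued against as the whole source: without a Foxp3 UMI, Ikzf2, Il2ra, Izumo1r, Tnfrsf18 and Ctla4 together stood at 0.905 (0.884 to 0.926) of their level in lymph node cells with one, and free RNA made up at most 17.2% (13.5 to 21.6) of UMIs there if it had the library's own profile, as the other UMIs of Birc5 lay in cycling-like cells. The kit and the Cell Ranger run may be the source, or the tissue itself, and these cannot be separated because each changes with the tissue in this design. The reporter allele changes the 3′ end of Foxp3, which could affect the Foxp3 counts of every library and was not tested.

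Resting T cell transcripts were higher in the epidermal than in the dermal library. Cells of the lymph node library mixed into epidermis were argued against as the whole source, since 43.3% (31.2 to 56.0) of the epidermal resting Treg-like cells held a Y-linked UMI and no lymph node cell did; cells of other male lymphoid tissue or blood were not tested. Free RNA as the whole source was argued against, since the excess UMIs spread by depth would reach more epidermal cells than held one. The median ratio of cells with a UMI to cells so reached was 0.692 (0.658 to 0.740) over the 14 list members higher in epidermis. Of these members, 10 lay below the range of such spreading and the others did not. Free RNA as a part of the source was not tested. A different mix of female and male animals as the whole source was argued against as well. The median was 0.92 (0.65 to 1.15) in cells with Xist and no Y-linked UMI and 0.97 (0.40 to 1.15) in cells with Y-linked and no Xist UMI. As part of the source the mix cannot be excluded, because both ranges lay below the 1.32 of all cells. The range of the cells with Xist also reached below the bound written for a lasting difference. A larger fraction of resting Tregs in epidermis may remain as a hypothesis, next to a part played by the mix of animals or by free RNA and to blood cells.

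Transcripts of the immediate early and dissociation list, which includes heat shock genes, were higher in the dermal than in the epidermal library. Without the immediate early-high clusters the list's median log2 ratio was -1.04 (-1.16 to -0.98), so the difference was not confined to those clusters. This cannot decide on a few strongly stressed cells as the source, because members of the list named the clusters left out. These clusters held 25.8% (20.7 to 31.5) of epidermal and 21.5% (18.7 to 24.4) of dermal cells, and they were defined within each library. The cells left out may thus not be alike, and leaving them out can itself move the ratio. A few cells weighed on Hspa1a and Hspa1b, as 5 of 838 dermal cells held 44.2% and 46.0% of their UMIs. Dilution by resting cells as the whole source was argued against, since without the resting Treg-like clusters the list's median was -0.69 (-0.76 to -0.63). The collagenase step cannot be told apart from the tissue, because dermis was the one digested tissue; the value it would have to account for is -0.91 in all gated cells. The digestion, a difference of the tissue and a few strongly stressed cells may all contribute.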

How the results depend on the processing

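Settings chosen after seeing the data are the ones on Xist, resting Treg-like clusters, the 20% mitochondrial limit, the 95th UMI percentile, immediate early-high clusters and cycling clusters. No gene called in the main values was called the other way in any setting run on the gene counts. Where all lists were run, 42 to 49 of 60 medians were apart, against 48 in the main values. Of planned list values, 411 of 700 stayed within counting error, 278 moved with the same direction or without a call and 11 reversed; of planned gene values these were 1790, 901 and 5 of 2696. The effector, immediate early, interferon, type 2 and proliferation lists stayed apart between epidermis and dermis in all 17 settings run on them. The cause of the changes was not tested unless the setting itself gives it, as for fewer genes passing a stricter limit. No paired analysis was possible because each tissue had 1 library and the labels number no animals. Depth limits the ratios of scarce transcripts: 271 epidermal cells leave wide intervals at 50 CPM.

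With the mean of each cell's CPM, 93 genes were lower in epidermis than in dermis, and the TGF-beta median was 0.10. With thinned cells, 131 were higher in epidermis than in dermis, 180 lower than in lymph node, and the TGF-beta median between the skin layers was 0.15. With median-of-ratios scaling, 340 were higher and 298 lower in epidermis than in lymph node, 543 lower in dermis, and 298 higher and 256 lower in both skin layers. With TMM these were 290, 398, 677, 258 and 340. Without mitochondrial and ribosomal protein genes, 163 were higher in epidermis than in dermis, 232 lower in epidermis, 781 lower in dermis and 210 lower in both than in lymph node, and the co-inhibitory median for dermis over lymph node was -0.20.

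At 20 CPM, higher and lower counts were 226 and 224 for epidermis over dermis, 1161 and 186 for epidermis over lymph node, 1439 and 564 for dermis over lymph node, and 930 and 165 for both skin layers, with a TGF-beta median of 0.14 between the skin layers. At 100 CPM they were 37 and 86, 260 and 64, 455 and 171, and 228 and 61 in the same order. With the interval beyond 2-fold, 47 were higher and 75 lower in epidermis than in dermis, and 66 were lower in epidermis and 66 in both skin layers than in lymph node.

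With lymph node effector Treg-like clusters only, 324 were higher in epidermis and 262 in both skin layers. For epidermis, medians were then 0.11 for the resting, -0.082 for the integrin, -0.29 for the co-inhibitory, -0.092 for the cytotoxic and -0.11 for the type 17 list. Cxcr3 stood at -0.19, Klrg1 at -0.088, Ly6a at -0.063 and Ly6c1 at 0.11. Cxcr3 and Klrg1 are on the effector marker list that named these clusters, so their values depend on that choice. The type 17 median for dermis was -0.32.

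In cells with a Foxp3 UMI, the Treg core median between the skin layers was -0.015 and Foxp3 for epidermis over lymph node was -0.33, the latter by choice of the cells. In cells with Xist and no Y-linked UMI, 89 were lower in epidermis than in dermis, and medians were 0.042 for residency, 0.081 for TGF-beta, 0.16 for T cell receptor activation and 0.069 for cytokines. Without resting Treg-like clusters the residency median was 0.031. Without cells above the 95th UMI percentile Rrm2 stood at -0.12 between the skin layers. Without cycling clusters Hist1h2ae stood at -0.049 between the skin layers and Birc5 at -0.97 for epidermis over lymph node, the latter on 2 epidermal UMIs. The share of cells with a Foxp3 UMI was 10.4%, 15.3% and 2.25% at 1000 UMIs and 43.2%, 48.6% and 7.18% without thinning, for epidermis, dermis and lymph node, since more UMIs per cell show more transcripts.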

Other observations

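The rule for cluster names and the shares of cycling transcripts were chosen after the data were seen, and no hypothesis was tested in this part.

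Each library fell into groups of cells that differed in Treg state; the genes that define a group are used only to describe it, and sizes are not compared between libraries, since the gene content, kits and depths differ. In lymph node, 1096 of 9300 cells (11.8%, 11.1 to 12.5) lay in effector Treg-like clusters, 478 (5.14%) in a cluster that the rule named immediate early-high-like but that was led by Nr4a3, Egr2 and Nr4a1 of the T cell receptor activation list, 383 (4.12%) in an interferon-high-like cluster and 91 (0.978%) in a cycling-like cluster. The interferon-high-like cells, led by Rsad2, Ifit3 and Isg15, had a median of 2922 UMIs. A separate group of 597 lymph node cells was led by the interferon-induced GTPase genes Gbp2, Iigp1 and Tgtp1. A group of 106 lymph node cells had the sterol synthesis genes Sqle and Hmgcs1 among its leading genes. Most lymph node cells, 7252 (78.0%), lay in clusters without a name, and none took the name resting Treg-like. Among the unnamed, a group of 1554 cells had the resting markers Satb1 and Igfbp4 among its leading genes. Names rest on markers raised over the other cells of the same library, so a missing name does not show that a state was absent.

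In epidermis, 70 of 271 cells (25.8%, 20.7 to 31.5) were immediate early-high-like, 67 (24.7%) resting Treg-like, 62 (22.9%) effector Treg-like and 8 (2.95%) cycling-like. A further 64 epidermal cells took no name. They were led by Serpinb1a, Lgals3 and the eotaxin receptor gene Ccr3. In dermis, 180 of 838 cells (21.5%, 18.7 to 24.4) were immediate early-high-like, 129 (15.4%) resting Treg-like with 6 resting and also 7 interferon-high markers raised, 116 (13.8%) effector Treg-like and 27 (3.22%) cycling-like. The other 386 dermal cells (46.1%) took no name. Of these, a group of 90 was led by Tff1, Pxdc1 and Cxcr6, with Il10 and Itgb8 among its leading genes. Y-linked UMIs were found in 43.3% of epidermal and 14% of dermal resting Treg-like cells, against 35.3% and 7.33% of the other cells of each library.

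Cycling-like cells held 47.8% of the UMIs of the proliferation list in epidermis, 17.6% in dermis and 16.6% in lymph node. They held 98.2% of Birc5 UMIs in epidermis (8 cells), 97.1% in dermis (27 cells) and 83.2% in lymph node (91 cells). For Mki67 the shares were 77.4%, 25.7% and 62.6%.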
